A study of Mus musculus with 48 samples.

How the data were processed

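The data were 4 tables of counts deposited by the authors, 1 per RNA class and B cell source, each with 12 libraries. Per the labels they hold 48 libraries in 16 groups of 3: primary splenic B cells of C57BL/6 mice or the mouse B lymphoma line CH12F3, cells or extracellular vesicles (EVs), day 1 or day 4, small RNA or long non-coding RNA. Every sample carries the same treatment tag, class switch recombination, and the labels do not state which day is stimulated, so the days were compared only as day 4 against day 1. The replicate numbers heading the columns (2, 3 and 4) differ from the experiment numbers in the sample titles (1, 2 and 3). Columns were therefore assigned to groups only, and libraries are called replicates 2, 3 and 4 here. Unused columns numbered 0. Whether the replicates are independent animals or cultures is not stated, so the p-values measure the spread between these samples.

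The submitters' processing notes name TopHat2 2.0, Cufflinks 2.0 and Cuffdiff with the mouse builds mm10 and GRCm38 for all samples. The program that made the counts and its annotation are not given in the sources used here. The labels describe Trizol and RNeasy extraction with on-column DNase, a NEBNext small RNA kit run on a MiSeq, and Ribo-Zero Gold depletion with the NEBNext Ultra kit run on a HiSeq with paired reads of 100 nt. The long RNA kit does not mark strand, so counts of antisense and overlapping genes are uncertain. Counts of near-identical copies (Mir92-1 and Mir92-2, Mir16-1 and Mir16-2, Mir19b-1 and Mir19b-2, Mir26a-1 and Mir26a-2, Gm43305 and its relatives) are uncertain as well. Gene types, coordinates and overlaps came from GENCODE M21 on GRCm38, in which all 2207 identifiers of the small RNA tables and all 9042 of the long RNA tables were found. All 2207 are annotated there as miRNA genes, among them Snord43, a small nucleolar RNA by name.

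Each comparison used the edgeR quasi-likelihood test (TMM factors, filterByExpr, robust fit) on the libraries of the groups compared, and p-values were adjusted by the Benjamini-Hochberg method over the RNAs tested in that comparison. A call is an adjusted p below 0.05, and "rose" and "fell" are used of calls only. Log2 fold changes are followed by ± standard error, computed as the absolute log2 fold change over the square root of F, and group means by ± standard deviation over 3 libraries. Percentages are of all counts in a library, without TMM. Where a group had 0 counts the fitted fold change has no meaning, and a lower bound is given instead, computed with 3 counts assumed over that group. Such bounds cover counting error only. A share of RNAs whose libraries did not overlap between groups is given for some comparisons. By chance, 10% of RNAs would separate 3 libraries from 3.

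Differences between day changes were fitted over 12 libraries: EVs minus cells within each source, and primary minus CH12F3 within each compartment. For the sources the pair of tables was joined by gene identifier. Gene lists (31, of which 13 had at least 3 measured members in some comparison and 5 had none in the tables) were tested with camera at a preset correlation of 0.01, 98 tests in all, adjusted over the tests of each RNA class. A list-wise count of calls "adjusted over the list alone" is given where it differs. The list of miRNA hosts includes Mirt1, which is not itself a miRNA host, and its counts and tests are those of the list with Mirt1. Agreements are Spearman rho across RNAs tested in both comparisons, and they are descriptive.

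Named RNAs were the 5 calls per direction with the largest log2 fold change among RNAs with no overlap between the libraries of the groups and a mean of at least 50 CPM in either group, the 4 most abundant and all called members of each list, and the 5 most abundant RNAs of each group. The replicate-wise Xist counts, the RNAs with the tRNA primer binding site and the RNAs named for differences between sources were chosen after their values were seen. Comparisons, lists, tests, named-RNA rule and the alternatives for scaling, filtering, tool, joint fit, replicate block and leaving out each library were fixed before the data were examined. Leaving out 4 RNAs from the totals, and leaving out both replicate-2 primary cell libraries, were added after seeing the results. The result for 1 RNA that the named-RNA rule selects is not reported here.

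Whether replicate numbers pair libraries across groups was checked by correlating residuals from group means, with Xist left out. To pass, r had to exceed 0.1 for each replicate number. Only the day comparisons of CH12F3 small RNA passed, in cells (r 0.286 to 0.451) and in EVs (r 0.251 to 0.584), and the blocked counts are printed for them. CH12F3 long RNA of cells between days, and of EVs against cells at each day, failed at r from 0.018 to 0.230. There, however, all 3 libraries matched their own replicate number best. Low Xist counts in primary cell replicate 2 at each day (5 and 6) leave pairing of primary cells across days open. Among 48 pairs of replicate libraries none was identical, and the lowest chi-square per degree of freedom between a pair was 2.98, more than counting error alone gives.

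Counts simulated with known changes were passed through the same steps as a self-test. In primary long RNA of cells, day 4 against day 1, planted 2-fold changes were called for 24.2% of RNAs, 4-fold for 83.3% and 16-fold for 93.9%, with 0.561% false calls. The same values for CH12F3 cells were 56.1%, 93.9% and 92.4%. For CH12F3 long RNA of EVs against cells at day 4 they were 1.52%, 15.2% and 71.2%. Each simulation drew the groups compared from the same mean profile and planted as many increases as decreases. The large difference in composition between EV and cell libraries was not simulated. The values for EVs against cells therefore do not describe recovery or false calls under it. In primary small RNA between the days, with 2 RNAs planted at each fold, no 2-fold or 4-fold change was called in cells or EVs. None was called in the wrong direction.

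Software versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.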

Results

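The libraries held RNA of mouse B cells and of the EVs they release. All were labelled class switch recombination, the DNA rearrangement by which a B cell changes the class of its antibody, and which day was stimulated is not stated. Primary B cells came from C57BL/6 spleens, and CH12F3 is a mouse B cell lymphoma line that switches in culture. Small RNA libraries were shallow, with 662 to 17104 counts in the primary table and 3990 to 40769 in the CH12F3 table, and long RNA libraries held 44731 to 791886 and 196452 to 1351695 counts. Primary EV libraries of long RNA detected 60 to 364 RNAs, against 3928 to 4750 in primary cells. Snord43 and 1 long RNA, Gm43305, made up most counts of cell small RNA and EV long RNA respectively. In primary cells Xist, the RNA that coats the inactive X chromosome, had 5 and 6 counts in replicate 2 at days 1 and 4 against 5800 to 17229 in the other replicates, and RNAs of the Y chromosome had 43 to 219 counts in each of these libraries.

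Long RNA of primary EVs was dominated by Gm43305, a processed transcript on chromosome 14 (54292443-54297456). It took 2.59 ± 0.22% of counts in cells and 90.7 ± 2.00% in EVs at day 1, and 7.05 ± 0.95% and 91.3 ± 1.17% at day 4 (n = 3 per group). Malat1, an abundant RNA retained in the nucleus, took 52.3 ± 1.87% of cell counts at day 1 and 29.5 ± 4.18% at day 4, and its EV shares were 0.0431% and 0.0668%. Beside Gm43305 (log2 fold change 8.86 ± 1.09, adjusted p = 0.000155 at day 1 and 7.27 ± 1.68, adjusted p = 0.00619 at day 4), the RNAs highest in EVs over cells were Gm42428 (10.24 ± 1.37 and 7.24 ± 1.55), Gm48275 (9.41 ± 1.12 and 7.29 ± 1.05), Gm42031 (8.63 ± 1.14 and 6.65 ± 1.60) and Gm35279 (8.31 ± 1.04 and 6.11 ± 1.19). With library totals in place of TMM, Gm43305 was at 5.04 and 3.54 and Gm42031 at 4.73 and 2.78. Most other long RNAs were lower in EVs. Malat1 fell by 5.91 ± 2.13 log2 units at day 1 (adjusted p = 0.0237) and 4.38 ± 1.69 at day 4 (adjusted p = 0.0314), and Neat1, the scaffold of nuclear paraspeckles, by 8.14 ± 1.35 and 6.54 ± 1.52. At day 1 1810026B05Rik was at least 369.7-fold lower in EVs, with 0 counts there and 6450 in cells, BE692007 at least 279-fold, Gm15675 at least 229-fold, AI504432 at least 186-fold and Mirt1 at least 138-fold. At day 4 Tug1 was at least 191-fold lower, with 0 counts in EVs and 8470 in cells, 1810026B05Rik at least 75.2-fold, Brip1os at least 67.3-fold, Dleu2 at least 63.9-fold and Gm20559 at least 57.6-fold.

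**Figure D1:**
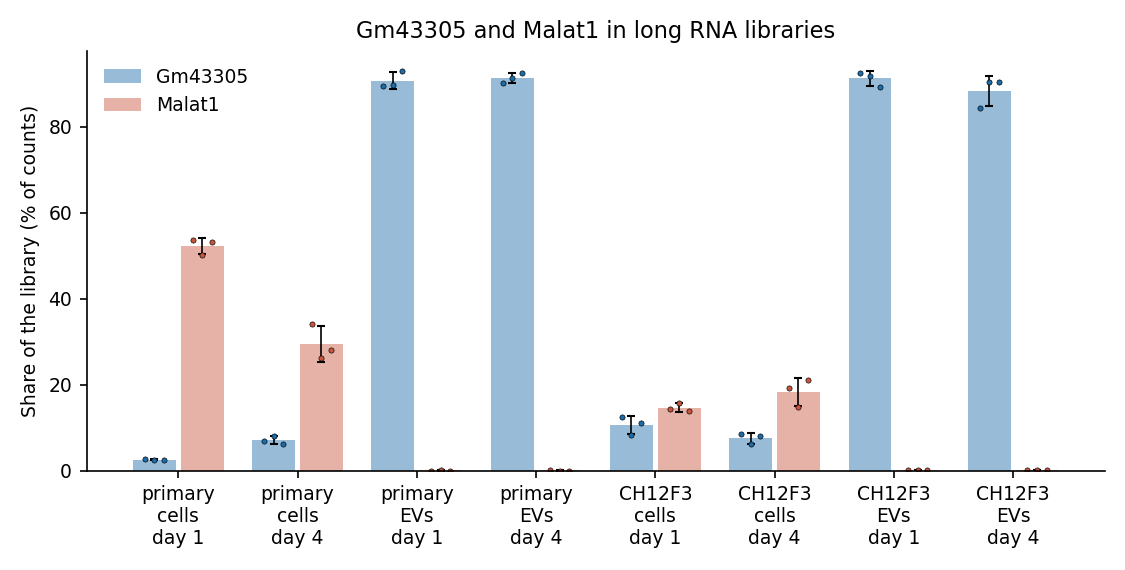
Share of library counts (percent, y axis) on Gm43305 and on Malat1 in each long RNA group (x axis). Bars are means, error bars standard deviations and points the 3 libraries.

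Transcripts that host snoRNAs in their introns fell as a group in primary EVs: 13 of 14 measured at day 1 (list test adjusted p = 0.0134, and 0.696 with an estimated correlation and 0.0593 with library totals) and 14 of 14 at day 4 (adjusted p = 0.00311, and 0.603 with an estimated correlation). Among them Gas5 fell by 5.45 ± 0.70 and 5.29 ± 1.47, and Snhg1 was at least 124-fold lower at day 1 and fell by 6.74 ± 1.11 at day 4. On the list of miRNA hosts 6 of 7 RNAs fell at day 1 (adjusted p = 0.142) and 7 of 7 at day 4 (adjusted p = 0.0259, and 0.603 with an estimated correlation). Mir155hg, the host of miR-155, was at least 6.90-fold lower at day 1 and at least 46.5-fold at day 4, and Mir142hg at least 30.2-fold and at least 16.3-fold. Nuclear-retained RNAs fell in 7 of 7 and 8 of 8 cases without a list call (adjusted p = 0.4 and 0.0866, and 0.877 and 0.000421 with library totals). All 6 imprinted RNAs measured at day 4 fell while the list test, which compares them with the other RNAs, gave the opposite direction (adjusted p = 0.981), and Peg13 was at least 7.62-fold lower there. At day 1, 21 RNAs rose and 1124 fell of 1212 tested, and at day 4, 22 rose and 712 fell of 833. TMM rested here on the few RNAs detected in EVs. Library totals moved the median log2 fold change from -6.79 to -8.14 at day 1 and from -6.80 to -7.76 at day 4, and DESeq2 called 2309 and 1607. A replicate block left 12 and 2 calls, and no pairing of replicates was seen in these comparisons.

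In CH12F3, too, Gm43305, Gm42428 and Gm35279 were among the RNAs highest in EVs over cells. Gm43305 took 10.6 ± 2.06% of cell counts and 91.2 ± 1.70% of EV counts at day 1, and 7.56 ± 1.26% and 88.3 ± 3.53% at day 4. Its log2 fold change was 8.60 ± 0.35 (adjusted p = 1.2e-127) at day 1 and 7.90 ± 0.58 (adjusted p = 0.000234) at day 4, beside Gm42428 (8.95 ± 0.48 and 8.32 ± 1.05), Gm35279 (8.62 ± 0.35 and 7.68 ± 0.61), Gm20400 (8.07 ± 0.40 and 7.23 ± 0.75) and Gm4316 (7.84 ± 0.34 and 6.72 ± 0.59). With library totals Gm43305 was at 3.07 and 3.52 and Gm4316 at 2.29 and 2.33. Mir17hg, the host of the miR-17-92 cluster, fell by 2.72 ± 0.29 at day 1 (adjusted p = 3.0e-15) and 4.67 ± 0.65 at day 4 (adjusted p = 0.00372). Also lower in EVs were Gm26789 (-3.91 ± 0.73), 6720427I07Rik (-2.93 ± 0.50), 2900076A07Rik (-2.81 ± 0.58) and Gm26981 (-2.58 ± 0.56) at day 1, and Gm15344 (-4.76 ± 0.99), Gm26628 (-4.68 ± 0.98), Gm12940 (-3.94 ± 0.60) and Mir155hg (-3.93 ± 0.57) at day 4. Pvt1, a long RNA transcribed beside Myc, was higher relative to the other RNAs under TMM (2.5 ± 0.27 and 2.46 ± 0.55), and with library totals its values were -2.98 and -1.96. At day 1 2900097C17Rik (1.80 ± 0.26) and Snhg8 (1.24 ± 0.26) rose under TMM and were at -3.67 and -4.24 with totals.

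Nuclear-retained RNAs fell in 4 of 8 cases in CH12F3 EVs at day 1 (list test adjusted p = 0.0191, and 0.603 with an estimated correlation and 0.0980 with library totals): Malat1 (-1.39 ± 0.26), Neat1 (-1.24 ± 0.25), Kcnq1ot1 (-1.20 ± 0.25) and Firre (-1.71 ± 0.37). At day 4, 1 of 8 fell, or 3 adjusted over the list alone (adjusted p = 0.0866, and 0.00168 with library totals), with Malat1 at -2.81 ± 0.49. On the list of miRNA hosts 5 of 8 and 4 of 8 RNAs fell (adjusted p = 0.0866 at each day), among them Dleu2 (-1.98 ± 0.34 and -2.69 ± 0.52), the host of miR-15a and miR-16-1, and Mir142hg (-2.52 ± 0.53 and -3.32 ± 0.68). At day 1, 83 RNAs rose and 95 fell of 1569 tested, and 38.0% of RNAs had no overlap between groups against 10% by chance. At day 4, 25 rose and 16 fell of 1288, with 36.3% not overlapping. The split depended on scaling: library totals moved the medians by -5.25 and -4.11 log2 units and gave 9 higher and 1555 lower at day 1 and 10 higher and 1033 lower at day 4. The day 4 count was 238 without EVs replicate 2, 22 without EVs replicate 3, and 11, 12 and 11 without cells replicates 2, 3 and 4. At day 1 it was 104 and 101 without EVs replicates 3 and 4. EVs day 4 replicate 2 detected 5390 RNAs, against 1521 and 1515 in replicates 3 and 4.

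**Figure D2:**
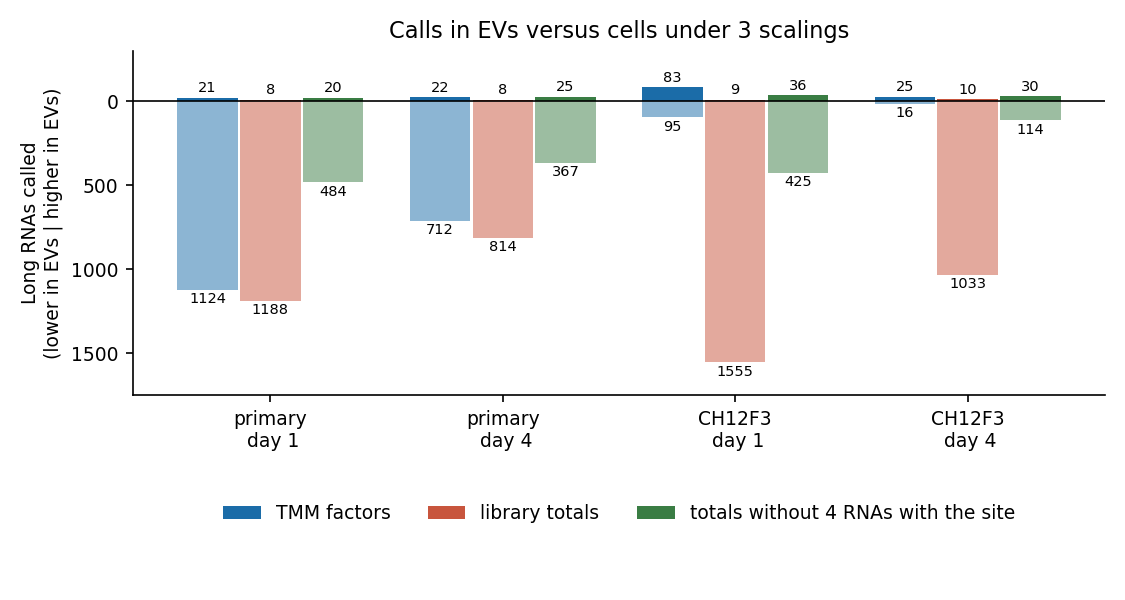
Number of RNAs called higher or lower in EVs than in cells (y axis) in the 4 long RNA comparisons (x axis). Calls are shown with TMM, with library totals and with totals that leave out 4 RNAs carrying a tRNA primer binding site.

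Primary B cells differed widely between day 4 and day 1. Mir155hg rose by 4.38 ± 0.36 log2 units (adjusted p = 5.7e-06), Trp53cor1, a target of p53, by 5.0 ± 0.72 (adjusted p = 0.000318), Pvt1 by 1.95 ± 0.27 (adjusted p = 0.000239) and 2900097C17Rik by 1.18 ± 0.23. With these, 4 of 5 measured immune, stress and p53-linked RNAs rose, or 5 adjusted over the list alone (list test adjusted p = 7.5e-05, and 0.603 with an estimated correlation). Gm13067 was at least 57.4-fold higher with 0 counts at day 1, and AU015791 (6.41 ± 1.15), Gm47418 (6.12 ± 0.38) and Gm13994 (5.18 ± 0.73) rose too. Of 16 snoRNA hosts 10 rose and none fell, or 11 adjusted over the list alone (list test adjusted p = 0.000612, and 0.603 with an estimated correlation), with Snhg15 at 2.65 ± 0.31, Rab26os at 2.72 ± 0.38, Snhg6 at 1.76 ± 0.24, Zfas1 at 1.38 ± 0.25 and Gas5 at 0.73 ± 0.21. Gm26917, an abundant RNA, rose by 3.08 ± 0.25 (adjusted p = 5.7e-06) and Gm43305 by 1.57 ± 0.19 (adjusted p = 8.4e-05). Whether counts of Gm26917 come from rRNA left after the Ribo-Zero depletion was not tested.

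On the falling side of the primary cells, Malat1 fell by 0.69 ± 0.17 (adjusted p = 0.0105) and Ftx, a nuclear RNA of the X-inactivation centre, by 1.09 ± 0.23 (adjusted p = 0.00476). The largest decreases were those of Gm47730, at least 19.3-fold lower with 0 counts at day 4, Gm19951 (-6.36 ± 0.58), Gm39321 (-5.29 ± 0.44), Gm9889 (-4.60 ± 0.66) and Gm11690 (-4.47 ± 0.68). Mirt1 fell by 3.17 ± 0.38 and the imprinted Peg13 by 2.39 ± 0.36, while the imprinted Nespas and Airn rose by 4.98 ± 0.68 and 2.11 ± 0.55. Of 9 nuclear-retained RNAs 2 rose and 2 fell (adjusted p = 0.604). Of 7 RNAs on the list of miRNA hosts 3 rose and 1, Mirt1, fell (adjusted p = 0.187), and of 6 imprinted RNAs 2 rose and 1 fell (adjusted p = 0.536). In all 166 RNAs rose and 144 fell of 1395 tested, and 38.6% did not overlap between days against 10% by chance. Library totals shifted the median by -0.12 and the share of calls that rose from 53.5% to 44.7%. Without cells day 1 replicate 2 the count was 198, and without both replicate-2 libraries, which had almost no Xist counts, 143.

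In CH12F3 cells several miRNA hosts and imprinted RNAs rose between day 1 and day 4. The miRNA hosts Mir17hg (1.44 ± 0.31, adjusted p = 0.00322), Mir142hg (1.45 ± 0.26), Dleu2 (0.82 ± 0.20) and Mir22hg (2.48 ± 0.40) rose. Mirt1, which is on their list without being a miRNA host, fell (-4.04 ± 0.34). The list thus had 4 up and 1 down of 8, or 5 and 1 adjusted over the list alone (list test adjusted p = 0.187). Imprinted RNAs rose in 3 of 5 cases (adjusted p = 0.103): Kcnq1ot1 (0.96 ± 0.22), Nespas (1.11 ± 0.30) and Peg13 (1.26 ± 0.32). Pvt1 and Trp53cor1, which rose in primary cells, fell by 0.68 ± 0.18 (adjusted p = 0.0109) and 1.43 ± 0.41 (adjusted p = 0.0183). Of 16 snoRNA hosts 2 rose, Rab26os (0.81 ± 0.23) and Dancr (1.47 ± 0.32), and 3 fell, Snhg1 (-0.60 ± 0.20), Snhg5 (-0.52 ± 0.17) and Epb41l4aos (-0.75 ± 0.24), or 2 and 7 adjusted over the list alone (list test adjusted p = 0.446). The largest increases were Gm14120 (5.57 ± 0.70), Gm34907 (5.08 ± 0.54), Gm30329 (4.42 ± 0.56), Gm20559 (3.31 ± 0.53) and Gm17322 (3.19 ± 0.39). The largest decreases were 4933407I05Rik (-6.39 ± 0.76), Gm6980 (-4.91 ± 0.52), which overlaps it on the other strand, Gm11755 (-4.81 ± 0.69) and Gm13348 (-4.47 ± 0.47). Of 1278 RNAs tested 111 rose and 157 fell, and 37.2% did not overlap against 10% by chance. With library totals the median moved by -0.11 and 81 rose and 177 fell.

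**Figure D3:**
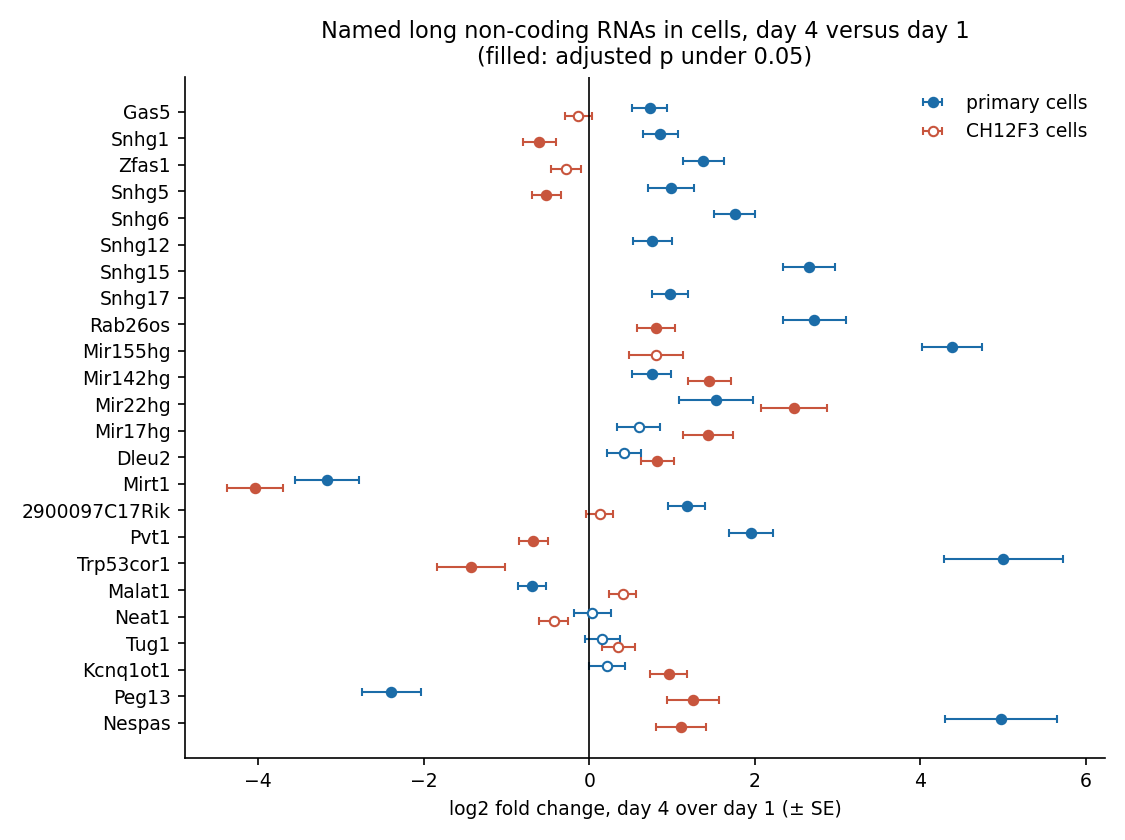
Log2 fold change of day 4 over day 1 (x axis) of 24 named long RNAs (y axis) in primary and CH12F3 cells. Points are estimates, bars standard errors, and filled points have an adjusted p below 0.05.

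Long RNA of EVs shared 1 increase between the sources: Gm26917 rose by 3.02 ± 0.70 in primary EVs (adjusted p = 0.0219) and 1.83 ± 0.34 in CH12F3 EVs (adjusted p = 0.0114). Residual rRNA as the source of these counts was not tested. In primary EVs Gm48275 (-2.45 ± 0.59), Gm42428 (-2.38 ± 0.49), Gm42031 (-1.44 ± 0.24) and Gm43305 (-0.83 ± 0.20) fell, although Gm43305 kept its share of counts and stood at 0.010 with library totals. In CH12F3 EVs Gm11998 (2.59 ± 0.44), Gm15987 (1.96 ± 0.42), Gm12000 (1.94 ± 0.49), which lies antisense to the lymphoid factor gene Ikzf1, and 2310015A10Rik (1.71 ± 0.41) rose. Gm17029 (-1.99 ± 0.39), D130062J10Rik (-1.71 ± 0.45), Lncpint (-1.68 ± 0.34) and BC051077 (-1.59 ± 0.37) fell. Malat1 passed the test in neither source (-0.01 ± 1.70 and -0.30 ± 0.29). The calls were 1 up and 4 down of 28 tested in primary EVs and 8 up and 4 down of 190 in CH12F3 EVs. With library totals they were 1 up and 0 down (median shift 0.75) and 10 up and 0 down (median shift 0.35), and DESeq2 called 0 in each. The primary count was 0, 3 and 2 without EVs day 4 replicates 2, 3 and 4. The CH12F3 count was 1, 0 and 0 without EVs day 1 replicates 2, 3 and 4, and 29, 0 and 7 without EVs day 4 replicates 2, 3 and 4.

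Small RNA of primary EVs held more of several miRNAs than the cells and less Snord43, a small nucleolar RNA that guides rRNA modification. Snord43 took 68.5 ± 19.3% of cell counts and 3.07 ± 3.07% of EV counts at day 1, and 50.6 ± 18.7% and 9.46 ± 5.51% at day 4. Its log2 fold change was -5.68 ± 1.69 (adjusted p = 0.00477) and -2.97 ± 0.92 (adjusted p = 0.00290). Mir5100 rose by 7.83 ± 1.47 at day 1 (464 counts against 1, adjusted p = 1.6e-05) and 7.13 ± 0.81 at day 4 (4265 against 8, adjusted p = 2.1e-14). Mir122, best known from liver, was at least 41.2-fold higher in EVs at day 1 and at least 36.2-fold at day 4, with 0 counts in cells. At day 4 Mir3963 was at least 49.98-fold higher, Mir19b-2 at least 31.0-fold, Mir101b at least 21.5-fold and Mir7004 at least 13.6-fold, each with 0 counts in cells. Mir423 (2.59 ± 0.67) and Mir10a (4.99 ± 1.66, 53 counts against 1) rose at day 1. The precursor genes Gm26340 (-2.77 ± 0.98 and -2.86 ± 0.62) and Gm23766 (-2.56 ± 0.86 and -3.88 ± 0.65) fell on each day, Mir92-2 fell at day 1 (-1.65 ± 0.56), and Gm25911 (-3.19 ± 0.88) and Gm22402 (-3.10 ± 0.78) fell at day 4.

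All 7 measured miRNAs of resting mature B cells rose in primary EVs at day 4 (list test adjusted p = 0.261), among them Mir150 (1.72 ± 0.63), Mir342 (2.89 ± 0.78), Mir26b (4.46 ± 0.93) and Mir30c-1 (3.22 ± 0.95). At day 1, 2 of 6 rose, Mir26a-1 (2.43 ± 0.64) and Mir26b (2.60 ± 0.67), with adjusted p = 0.423 for the list. Of the miRNAs induced in activated lymphocytes 3 of 3 rose at day 4 (adjusted p = 0.577): Mir146 (2.57 ± 0.71), Mir222 (2.58 ± 0.79) and Mir221 (2.03 ± 0.78). In the miR-15/16 family 2 of 3 rose, Mir16-1 (3.62 ± 0.88) and Mir16-2 (5.21 ± 1.18), with adjusted p = 0.815. The let-7 list had 1 call of 3, Mirlet7g (2.52 ± 0.79), and a list test in the opposite direction from its median (adjusted p = 0.823). At day 1, 6 RNAs rose and 4 fell of 26 tested (50% not overlapping, 10% by chance), and at day 4, 30 rose and 10 fell of 57 (71.9%). Library totals shifted the medians by 1.39 and 0.72 and gave 7 up and 1 down at day 1 and 34 up and 8 down at day 4. The day 1 count was 6 without cells replicate 3 or replicate 4, and the day 4 count 26 without cells replicate 2.

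Snord43 was lower in CH12F3 EVs as well, and Mir5100, Mir3963 and Mir7004 were called higher in EVs in each source. Snord43 took 76.3 ± 4.43% of cell counts and 28.8 ± 8.88% of EV counts at day 1 (log2 fold change -3.26 ± 0.43, adjusted p = 0.000132), and 73.7 ± 3.81% and 39.0 ± 15.8% at day 4 (-2.19 ± 0.64, adjusted p = 0.0124). Late-registered miRNA genes (high miRBase numbers) rose in 5 of 5 cases at day 1 (list test adjusted p = 0.000752, and 0.721 with an estimated correlation): Mir7004 (at least 11.3-fold, 0 counts in cells), Mir6406 (5.06 ± 0.80), Mir5100 (3.18 ± 0.79), Mir3963 (2.73 ± 0.69) and Mir6236 (2.44 ± 0.74). At day 4, 2 of 3 rose, or 3 adjusted over the list alone (adjusted p = 0.0188, and 0.721 with an estimated correlation and 0.0533 with library totals), Mir6236 (4.79 ± 1.18) and Mir3963 (4.66 ± 0.95). In primary EVs at day 4, 3 of 6 measured RNAs on this list rose, without a list call (adjusted p = 0.391). Gm23935 rose in CH12F3 EVs at day 1 (2.80 ± 0.76) and day 4 (3.10 ± 0.45, adjusted p = 4.9e-06). It fell in primary EVs at day 4 (-2.04 ± 0.64, adjusted p = 0.00312). Also higher in CH12F3 EVs at day 4 were Gm24187 (4.08 ± 0.92), Gm24270 (4.01 ± 1.36) and Gm44391 (3.53 ± 1.01). In CH12F3 EVs Mir19b-2 (-3.04 ± 0.73), Mir9-3 (-3.02 ± 0.80), Mir15b (-3.0 ± 0.95), Mir101b (-2.80 ± 0.93), Mirlet7a-2 (-2.77 ± 0.92) and Mir26b (-2.63 ± 0.84) fell at day 1, and Mir103-1 (-2.40 ± 0.47) and Mir26a-1 (-1.68 ± 0.47) at day 4. Mir19b-2, Mir101b and Mir26b thus fell in CH12F3 EVs at day 1 and were higher in primary EVs at day 4.

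Counts of calls in CH12F3 small RNA depended on scaling and on single libraries. Of 59 RNAs tested at day 1, 6 rose and 7 fell (55.9% not overlapping, 10% by chance), and of 57 at day 4, 7 rose and 3 fell (49.1%). With library totals the medians moved by 1.81 and 1.36, and 29 RNAs were higher and 1 lower at day 1, and 21 higher and 0 lower at day 4. The lower miRNAs named from CH12F3 EVs were thus lower relative to the other small RNAs. Leaving out EVs day 1 replicates 2, 3 and 4 gave 34, 4 and 1 calls, and leaving out cells day 1 replicates 3 and 4 gave 8 and 5. At day 4 the count was 35, 17 and 17 without EVs replicates 2, 3 and 4.

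**Figure D4:**
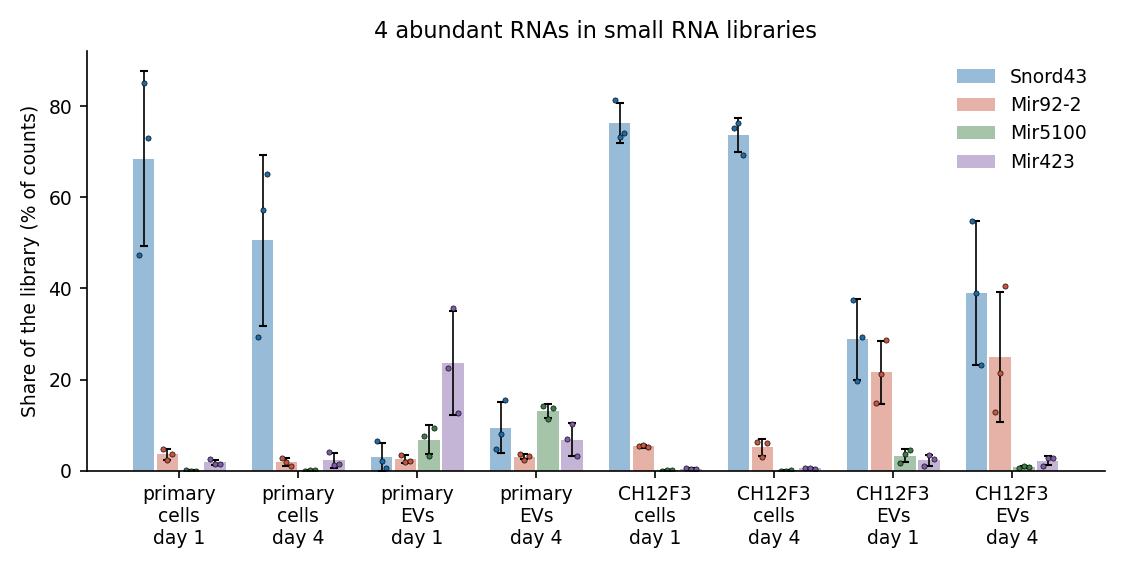
Share of library counts (percent, y axis) on Snord43, Mir92-2, Mir5100 and Mir423 in each small RNA group (x axis). Bars are means, error bars standard deviations and points the 3 libraries.

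Few small RNAs were called between the days. In CH12F3 cells Mir10b rose by 1.48 ± 0.31 (332 to 1219 counts, adjusted p = 0.000241) and Mir146b by 1.95 ± 0.46 (27 to 146 counts, adjusted p = 0.00100). Mir5100 fell by 1.74 ± 0.41 in CH12F3 EVs (adjusted p = 0.0367) and Mir6406 went from 76 counts to 1 (adjusted p = 0.0274). Snord43 passed the test in neither cell source (-1.08 ± 0.89 in primary cells, -0.41 ± 0.26 in CH12F3 cells). These 2 CH12F3 comparisons showed paired replicates, and with a replicate block 5 RNAs rose and 4 fell in cells and 1 rose and 2 fell in EVs. Without the block the calls were 2 of 60 in cells and 2 of 37 in EVs. The CH12F3 cell count was 5 with library totals (median shift 0.36), 1 without cells day 1 replicate 3 and 4 without cells day 4 replicate 4. The CH12F3 EV count was 0 without EVs day 1 replicate 3 or replicate 4, and 4, 1 and 1 without EVs day 4 replicates 2, 3 and 4 (median shift with totals -0.22).

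In primary small RNA edgeR called 0 RNAs between the days, in cells (28 tested, 5 at unadjusted p < 0.05, DESeq2 0) and in EVs (59 tested, 10 at unadjusted p < 0.05, DESeq2 1). Mir150 in cells (-1.75 ± 0.72, adjusted p = 0.234), Mir181a-1 in cells (-1.87 ± 0.78, adjusted p = 0.234), Mir146 in EVs (1.83 ± 0.75, adjusted p = 0.156) and Mir16-1 in EVs (4.18 ± 1.32, adjusted p = 0.103) stayed short of the threshold. None of 5 measured hematopoietic miRNAs passed in cells (list test adjusted p = 0.0992). Of 2 simulated 4-fold changes each, 2 were tested in cells and 1 in EVs and none was called, so 0 calls leave room for changes of that size. RLE factors gave 4 calls in cells, 1 up and 3 down, and totals shifted their median by 0.48. Without cells day 1 replicate 2 the cells gave 12. The EV count was 4, 1 and 3 without EVs day 1 replicates 2, 3 and 4, and 5 without EVs day 4 replicate 3.

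Whether EVs changed between the days otherwise than cells was tested in each table, and edgeR called 0 RNAs in all 4. At unadjusted p < 0.05 there were 8 of 68 in primary small RNA, 84 of 1424 in primary long RNA, 10 of 77 in CH12F3 small RNA and 176 of 1713 in CH12F3 long RNA, and DESeq2 called 0, 37, 0 and 0. In CH12F3 long RNA the snoRNA hosts as a list were lower in this difference (0 of 16 called, adjusted p = 0.00753, and 0.696 with an estimated correlation and 0.590 with library totals). Median shifts with totals were -0.48, 0.10, -0.37 and 1.10, with 0, 11, 2 and 0 calls. Single libraries changed the 0: EVs day 4 replicates 2 and 4 gave 14 and 10 in CH12F3 long RNA when left out, and EVs day 4 replicate 3 gave 2 in primary long RNA. In CH12F3 small RNA leaving out EVs day 1 replicate 3, cells day 4 replicate 2 or EVs day 4 replicate 2 gave 3, 1 and 4. In primary small RNA leaving out cells day 1 replicate 2 gave 8, EVs day 1 replicates 2, 3 and 4 gave 4, 1 and 2, cells day 4 replicates 2 and 4 gave 2 and 1, and EVs day 4 replicate 3 gave 1.

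Spearman rho of the EV against cell difference between day 1 and day 4 was 0.83 over 24 small RNAs and 0.48 over 759 long RNAs in primary samples, and 0.85 over 50 and 0.46 over 1172 in CH12F3. Between primary and CH12F3 it was 0.12 over 953 long RNAs at day 1 and 0.42 over 743 at day 4, and 0.17 and -0.43 in small RNA. Under TMM, long RNAs higher in EVs were shared more often than independent lists would give, 17 against 1.30 at day 1 and 14 against 0.549 at day 4. Gm43305 and Gm42428 were among them. With library totals fewer RNAs than these were higher in CH12F3 EVs, so overlaps of this size exist under TMM only. Counts of Gm43305 and its near-identical relatives may also not be independent. The day change in cells had rho -0.08 between the sources over 987 long RNAs, with 16 shared increases against 11.9 and 8 shared decreases against 7.15. Rab26os and Nespas rose and Mirt1 fell in each source, while Pvt1 and Trp53cor1 rose in primary cells and fell in CH12F3 cells. In small RNA it gave rho 0.23 in cells and -0.29 in EVs, and in long RNA of EVs 0.04. Between cells and EVs of a source the day changes had rho 0.30 (primary small), 0.03 (primary long), 0.35 (CH12F3 small) and 0.55 (CH12F3 long).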

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

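A set of comparisons asked whether the day change differed between primary and CH12F3 samples, and 3 of them gave calls that set the sources apart. These tests were chosen before the data were examined, while the RNAs named below were chosen after their values were seen. In small RNA of EVs 6 RNAs differed, 5 with a positive difference (primary minus CH12F3 log2 change) and 1 with a negative one. Mir5100 had a log2 fold change of 0.93 in primary EVs (adjusted p = 0.489) and -1.74 in CH12F3 EVs (adjusted p = 0.0367), a difference of 3.36 ± 0.99 (adjusted p = 0.0133). Mir6406 was at 0.26 (adjusted p = 0.857) and -5.77 (adjusted p = 0.0274), and Mir19b-2 at 3.27 (adjusted p = 0.140) and -1.60 (adjusted p = 0.682). Gm23193, Mir222 and Mir342 were the others, and none of the 6 was called between the days in primary EVs alone. With totals in place of TMM the split was 6 and 3 and the median moved by -0.26, and DESeq2 called 3. The count was 16 without primary EVs day 1 replicate 2, 3 without CH12F3 EVs day 1 replicate 4 and 19 without CH12F3 EVs day 4 replicate 2.

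In long RNA of cells 344 RNAs differed, 201 with a positive and 143 with a negative difference of primary minus CH12F3. Gm15848 fell in primary cells (-2.41) and rose in CH12F3 cells (3.04), a difference of -5.54 ± 0.46 (adjusted p = 9.7e-08), and 2010309G21Rik did likewise (-2.95 and 1.41, adjusted p = 1.5e-07). Gm42047 rose in primary cells (4.63) and fell slightly in CH12F3 cells (-0.46), as did Gm47761 (4.28 and -0.57). Gm15675 fell in primary cells (-3.91) and did not pass the test in CH12F3 (-0.35).

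In long RNA of EVs 8 RNAs differed, all with a positive difference of primary minus CH12F3: 4933404O12Rik, Gm47283, 1810032O08Rik, Snhg15, BX649560.1, 5031425E22Rik, Gm30414 and A730017L22Rik. Each had 0 counts in primary EVs at day 1 and 7 to 17 at day 4, so these calls rest on few counts. RLE factors, DESeq2, no filter and a replicate block each gave 0 calls, and so did leaving out primary EVs day 1 replicate 2 or 4, primary EVs day 4 replicate 2, or any CH12F3 EV library except day 4 replicate 2. Without primary EVs day 4 replicate 3 the count was 1. The median moved by -0.26 with totals. In small RNA of cells edgeR called 0 differences, with 6 at unadjusted p < 0.05 of 72 tested and 0 by DESeq2. Leaving out primary cells day 1 replicate 2 gave 13 and primary cells day 4 replicate 3 gave 1.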

How the results depend on the processing

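The alternatives were chosen before the results were seen, except the tests on totals without 4 RNAs and without both replicate-2 cell libraries. Values are calls unless stated, and the cause of a change was not tested. Without the low-count filter primary small RNA gave 3 (EVs against cells, day 1), 15 (day 4) and 4 (days, EVs), primary long RNA 1796, 1184 and 3 for the same comparisons, CH12F3 small RNA 20 (day 1) and 1 (days, EVs), CH12F3 long RNA 478 (day 4), the difference of day changes 29 (primary long) and 2 (CH12F3 long), and the sources in long RNA of EVs 0. Agreements without the filter were 0.0968 (days, cells and EVs) and 0.562 (EV against cell, days) in primary small RNA, 0.0866 and 0.425 in CH12F3 small RNA, 0.176 and 0.219 in CH12F3 long RNA and -0.118 between the sources for small RNA at day 4. The agreement of the sources in small RNA of cells turned from 0.23 to -0.011. With 1 fit over 12 libraries primary small RNA gave 25 (day 1) and 2 (days, EVs), primary long RNA 187 (days, cells) and 0 (days, EVs), CH12F3 small RNA 28 (day 4), 0 (days, cells) and 5 (days, EVs), and CH12F3 long RNA 93 (day 1), 265 (day 4) and 74 (days, cells). RLE gave 4 (primary small, days, cells) and 0 (sources, long EVs). DESeq2 gave 1 (primary small, days, EVs), 2309, 1607 and 0 (primary long, day 1, day 4, days in EVs), 21, 19 and 1 (CH12F3 small, same order), 288 and 0 (CH12F3 long, day 4, days in EVs), 37 (primary long, difference of day changes), 3 (sources, small EVs) and 0 (sources, long EVs). Library totals gave 1 (primary long, days, EVs), 30, 21 and 5 (CH12F3 small, day 1, day 4, days in cells), 1564 and 1043 (CH12F3 long), 11 and 2 (difference of day changes, primary long and CH12F3 small) and 5 (sources, long EVs). Totals without the 4 RNAs with the primer binding site gave 504 and 392 in primary and 461 and 144 in CH12F3 long RNA. Gene list calls went from 9 to 0 with an estimated correlation. With totals there were 10, among them lower snoRNA hosts in CH12F3 EVs (adjusted p = 0.0312 and 3.9e-08, days 1 and 4) and a lower immune, stress and p53-linked list there at day 4 (0.0350).

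Signs of 14 named values turned with a call under the main or the other setting. Turned signs without a call were not counted. For example, Mir146 in CH12F3 EVs at day 1 was at -0.27 under TMM, with 0.932% of EV and 0.338% of cell counts. AI506816 in primary EVs at day 4 was at -1.14 with RLE, -1.16 with DESeq2 and -1.55 with totals. With totals AC160336.1 was at -0.37 in primary EVs at day 1, Gm43305 at 0.010 between days in primary EVs, and in CH12F3 EVs Snhg8 -4.24, 2900097C17Rik -3.67, Pvt1 -2.98, Gm42047 -0.88, AI506816 -0.77 and Gas5 -5.01 at day 1, and Pvt1 -1.96, Gm26917 -3.55 and Gm42047 -0.87 at day 4. Of the named values over all settings 3229 were labelled the same, 544 weaker and 63 stronger. Uncalled values whose sign turned are within these counts.

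Leaving out each library gave, lowest to highest, 6 to 12, 26 to 48, 0 to 12 and 0 to 5 in primary small RNA (EVs against cells at days 1 and 4, then days in cells and in EVs), 198 to 442 and 0 to 7 for the days in primary long RNA, 1 to 34, 7 to 35, 1 to 4 and 0 to 4 in CH12F3 small RNA, and 101 to 173, 11 to 238 and 0 to 29 in CH12F3 long RNA (days 1 and 4, days in EVs). Without both replicate-2 cell libraries primary long RNA of cells gave 143. Differences of day changes gave 0 to 8, 0 to 2, 0 to 4 and 0 to 14, and the sources 0 to 13 (small, cells), 3 to 19 (small, EVs) and 0 to 11 (long, EVs).

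With the replicate as a block the counts were 1 (primary small, days, EVs), 12 and 2 (primary long, EVs against cells), 9 (CH12F3 small, days, cells), 22 (CH12F3 long, day 4), 0 (sources, long EVs) and 5 list calls. Of the primary long RNA calls at day 4, 2 of 734 had the other sign with the block. Residual correlations passed the pairing check only for the days in CH12F3 small RNA. Small RNA libraries were shallow: those of primary EVs at day 1 held 662 to 4089 counts.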

Other observations

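Gm43305 made up most long RNA counts in EVs of primary B cells and of the CH12F3 lymphoma line, and the nuclear RNA Malat1 took a small share of them. Small RNA of EVs held less Snord43 than cells in each source. Between days 1 and 4 Mir155hg, Trp53cor1, Pvt1 and 10 of 16 snoRNA hosts rose in primary cells (list test adjusted p = 0.000612, and 0.603 with an estimated correlation). In CH12F3 cells Mir17hg rose and Trp53cor1 and Pvt1 fell, while Rab26os and Nespas rose and Mirt1 fell in each source. The tests of Gm42031 reads, genomic DNA, structural fragments and regrouped libraries were chosen before their results were seen, and the other tests in this part after.

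Gm43305, Gm42031 and Gm42047 hold an exact 18-nt primer binding site of tRNA-Gln, by which retroviral elements prime reverse transcription, and Gm4316 holds it with 1 mismatch; under TMM the median EV over cell log2 fold change of Gm42031, Gm42047 and Gm4316 lay at or above the 99.96 percentile of lists matched on cell level, but as they were chosen after their values were seen a retroviral origin was left open. The choice between TMM and library totals did not set the sign of Gm43305 in EVs over cells, whose lowest log2 fold change with totals was 3.07. Both scalings are relative to the counted RNA, so they cannot tell a gain of Gm43305 from a loss of the other RNAs. The sign of Gm42047 depended on the scaling: its values with totals were -2.82, -2.73, -0.88 and -0.87, beside medians over all RNAs of -8.14, -7.76, -5.88 and -4.36. With totals Gm42031 stayed called (lowest 1.99), while the call of Gm4316 in primary EVs at day 4 ended as its value went from 4.25 ± 1.25 (adjusted p = 0.0152) under TMM to 0.46 ± 0.41 (adjusted p = 0.281). A constant share of Gm43305 reads over both sources as the source of all counts was excluded. The highest over lowest group ratio to Gm43305 was 62.7 for Gm42031, 41.7 for Gm4316 and 3289.6 for Gm42047, each between groups of different sources. For Gm42031 the group means ran from 4.78% to 8.99% in primary and from 0.143% to 0.411% in CH12F3 samples. Its 62.7 thus came mostly from the difference between sources. Within CH12F3 the ratio was at most 0.205% in EV and at least 0.294% in cell libraries for Gm42031. For Gm4316 it was at most 3.69% and at least 5.56% there. In primary samples the libraries overlapped at day 1 for Gm42031, and as cells had the higher mean ratios, shared reads beside transcription of these genes in cells were left open for the EV counts.

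CH12F3 EVs day 4 replicate 2 detected 1796 of 4218 RNAs with 0 counts in all CH12F3 cell libraries (42.6%), against 44 and 43 in replicates 3 and 4. Their counts followed exonic length (Spearman rho 0.351), which fits genomic DNA, although the labels give an on-column DNase step. Longer RNAs also give more fragments, so this test cannot tell DNA from RNA at low levels. These RNAs held 0.776% of the counts of replicate 2. Counts outside the 10 top RNAs were 7.30% in replicate 2, which is 5.59% more than the mean of replicates 3 and 4. Cell RNA with the Malat1 share of day 4 cell libraries (18.4%) was excluded as the source of this added part. It would need Malat1 at 1.03% of counts, and Malat1 took 0.127%, against 0.130% in each of replicates 3 and 4. Malat1 is retained in the nucleus, so cytoplasmic RNA without it was left open.

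Late-registered miRNA genes rose in 5 of 5 cases at day 1 and 2 of 3 at day 4 in CH12F3 EVs (list test adjusted p = 0.000752 and 0.0188, and 0.721 at each day with an estimated correlation, and 0.0130 and 0.0533 with library totals). In primary EVs at day 4 the list was not called (3 of 6 rose, list test adjusted p = 0.391). Such genes could hold fragments of structural RNAs, although none of the 5 that rose in CH12F3 EVs at day 1 shared an 18-nt stretch with a structural RNA that was searched. Counting each RNA once per day, 1 of 13 small RNAs called higher in CH12F3 EVs shared such a stretch, against 16 of 103 other tested RNAs (Fisher exact p = 0.688), which cannot tell. In primary EVs it was 0 of 36 against 8 of 47 (Fisher exact p = 0.00874). These 8 all shared their stretch with the same structural RNA, and Gm23766 and Gm26340 were counted at each day. They are thus not independent, and no conclusion is drawn from that p-value. All small RNAs with a shared stretch had a positive log2 fold change (0.23 to 3.53) in CH12F3 EVs, called or not, and all in primary EVs a negative one. In CH12F3, too, all but Gm44391 shared it with that same structural RNA. The longest nuclear rRNA transcript searched was 1849 nt, too short for the large-subunit rRNA, and nuclear tRNAs were not searched, so fragments of these were left open.

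Libraries were also regrouped at random. With 3 against 3 libraries there are 10 splits, the real one included, so no share under 0.05 can arise. As many calls as the real split came from 1 of 10, the real split itself, in 13 comparisons. They came from 2 of 10 in CH12F3 small RNA of EVs between days. In the pair with 0 calls (primary small RNA between days) it was 10 of 10, which any regrouping gives, so it tells nothing. The highest count of any other split was 0 except for 1 (primary small, days, EVs, real 0), 1 (CH12F3 small, days, cells, real 2), 2 (CH12F3 small, days, EVs, real 2) and 2 (CH12F3 long, EVs against cells at day 1, real 178). The 100 drawn regroupings include the real one as well. All 100 gave as many calls as the 0 of each difference of day changes (highest other 4, 8, 4 and 35). The same held for the 0 of small RNA in cells between sources (highest other 1). With 0 real calls this outcome was fixed in advance. For the sources it was 2 of 100 in small RNA of EVs (real 6, highest other 6), 1 of 100 in long RNA of cells (real 344, highest other 132) and 1 of 100 in long RNA of EVs (real 8, highest other 6).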
